A study of Homo sapiens with 6 samples.

How the data were processed

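RNA was measured in 6 libraries of H23 cells, a human lung adenocarcinoma cell line. Per the labels, 3 libraries came from cells given a control siRNA and 3 from cells given an siRNA against HOTAIR-N, a form of the long non-coding RNA HOTAIR. Per the series' design text each library stands for an independent transfection, and RNA was taken 48 hours later. The labels name a stranded total RNA kit with ribosomal RNA depletion. The submitters' processing notes name STAR 2.6.0c, RSEM 1.3.0 and the genome build hg19, and the annotation release and the strand setting are not given in the sources used here.

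For each library the authors deposited a table of 27968 genes by symbol and a table of 70006 isoforms by RefSeq name. Both give expected counts, which per the file headers are RSEM's estimates of the reads of each gene or isoform, with reads that match several transcripts divided between them. The deposited gene values were not whole numbers in 10.9% of cases and the isoform values in 42.2%. The same tables hold TPM and FPKM, which per the file headers are length-adjusted values scaled by the authors within each library, and the isoform tables hold the percent of its gene that each isoform makes up, as deposited. Gene and transcript lengths were also taken from the deposited tables.

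The totals ranged from 32715361 to 36578681 expected counts per library. At that depth HOTAIR, at about 5 CPM with control siRNA, rests on 148 to 202 counts in a library, while isoform values carry in addition the error of dividing shared reads, which the tables do not state. Genes that share sequence with close copies, such as ribosomal protein, histone and readthrough genes, are uncertain for that reason. Overlapping and antisense genes are uncertain too, since the strand setting of the counting is not known.

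Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes passed the filterByExpr function by group, library sizes were scaled by TMM, and the robust quasi-likelihood test compared HOTAIR-N siRNA with control siRNA. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and log2 fold changes are HOTAIR-N siRNA minus control siRNA with their standard errors (SE). Values in CPM (counts scaled to library size) use the same scaled library sizes where a group mean is given. Isoforms were tested in the same way, and a change in isoform use within a gene was tested with edgeR's diffSpliceDGE function and Simes p-values. HOTAIR was also compared with an exact two-sided permutation test.

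The 40 gene lists, the tests of genes, isoforms, isoform use and lists, and their alternatives were set before the data were examined, except for the alternatives with a length and GC trend removed or with word-carrying list members left out. Those, and the search for words in sequences with the tests that rest on it, were added later. Lists with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The genes named were chosen by rule. They are HOTAIR and the HOXC cluster, the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1, a length of at least 200 nt and no overlap between the groups, and up to 4 members of each list with the smallest p. For isoforms they are the 5 with the smallest p whose gene did not pass, and the 5 genes with the smallest p for isoform use. Other genes named were chosen after their values were seen, and are marked so. Some genes that the rule takes are not reported here.

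Alternatives were RLE, upper-quartile and unscaled library sizes, no filter and a stricter filter, genes under 200 nt left out, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, and for lists an estimated correlation, the fry test and a prior count of 0.5. Simulated counts with 200 changed genes were run through the same steps. For the comparison of the siRNAs over 15072 genes, 82% of genes changed by a fold of 1.5 and 90% of those changed by a fold of 2 were called in the right direction, and 4.97% of calls were unchanged genes. Over 32627 isoforms, 27% of those changed by a fold of 2 were called. Over 7523 genes with several isoforms, 6.5% of genes whose most abundant isoform changed by a fold of 2 were called for isoform use, and 7.14% of the calls were unchanged genes. The last share rests on few calls. Each of these simulations changed 200 genes or isoforms, fewer than differed in the data, so the rates need not hold there.

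Words of 7 bases in 3' UTRs were related to the fold changes, after a trend with UTR length and GC content was removed. Sequences came from GENCODE release 29, on another genome build than the deposited tables, so that no coordinates were taken over, and 13298 of the 15072 tested genes had a 3' UTR of at least 50 nt there. The siRNA sequences are not given in the sources used here. In 5 of 5 simulated data sets, with fold changes shuffled among genes and a planted word that lowered them by 0.25, the planted word was found. Smaller shifts were not planted. Without a planted word z stayed between -3.99 and 4.07, but shuffling removes any link of fold changes to UTR sequence. In the real data the strongest words unrelated to the top word of each direction reached -4.77 and 4.60, outside that range.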

Results

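The transcriptomes of H23 lung adenocarcinoma cells were compared 48 hours after transfection of a control siRNA or an siRNA against HOTAIR-N, with 3 independent transfections each. Control libraries held 34715341, 35206646 and 36578681 expected counts, and HOTAIR-N siRNA libraries 32715361, 33667345 and 35329948. The first principal component, with 75.3% of the variance, separated the siRNAs. The lowest correlation of log2 CPM within a group was 0.994 and the highest between groups 0.977. All replicate pairs differed by more than sampling noise, most of all those with control replicate 1. The chi-square of counts per degree of freedom was 15.4 and 14 for control replicate 1 against 2 and 3. It was 7.33 for control replicates 2 and 3, and 2.12 to 6.12 within HOTAIR-N siRNA.

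The targeted gene was examined first. HOTAIR, a non-coding RNA transcribed from the HOXC cluster on chromosome 12 between HOXC12 and HOXC11, was lower in all 3 libraries with HOTAIR-N siRNA. Its expected counts were 169, 148 and 202 in the control libraries and 88, 74 and 82 in the HOTAIR-N siRNA libraries. This was 4.90 ± 0.67 CPM (SD, n = 3) against 2.39 ± 0.26 CPM (SD, n = 3), or 48.6% of control. The log2 fold change was -1.04 with an SE of 0.14 (edgeR quasi-likelihood test, adjusted p = 1.32e-05). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. No isoform in the tables is named HOTAIR-N, so the measured value covers the gene as annotated. Of its isoforms, NR_047517 had a log2 fold change of -1.19 (SE 0.35) and did not pass the test (edgeR, adjusted p = 0.069), and NR_047518 had -0.32 (SE 0.68).

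Elsewhere in the HOXC cluster, HOXC6 and HOXC8, homeobox transcription factors that do not lie next to HOTAIR, rose with HOTAIR-N siRNA. HOXC6 went from 3.49 ± 0.24 to 5.37 ± 0.19 CPM (SD, n = 3 each) and HOXC8 from 3.81 ± 0.20 to 5.54 ± 0.48 CPM (SD, n = 3 each), with log2 fold changes of 0.62 (SE 0.11) and 0.54 (SE 0.11). HOXC4 fell by 0.68 on the log2 scale (edgeR, adjusted p = 0.0172), but did not pass when control replicate 2 (adjusted p = 0.0975) or HOTAIR-N siRNA replicate 2 (adjusted p = 0.0792) was left out. HOXC10, the most abundant gene of the cluster, had a log2 fold change of -0.13 (SE 0.06) and did not pass (adjusted p = 0.0653). The other 7 tested genes of the cluster did not pass either. HOXC11 had a log2 fold change of 0.09, HOXC12 0.26, HOXC13 -0.10, HOXC9 -0.18, HOXC5 0.35, HOXC13-AS 0.15 and HOXC-AS3 -0.23. HOXC5 passed without control replicate 3, at 0.68 (adjusted p = 0.0134), and with a trend with length and GC content removed, an alternative chosen after the data were seen, HOXC10 (-0.14, adjusted p = 0.00323), HOXC13 (-0.15, adjusted p = 0.0378) and HOXC-AS3 (-0.69, adjusted p = 0.0386) passed. Over the list of 12 tested genes, 2 rose, 2 fell including HOTAIR itself, and 8 did not pass, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.945).

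**Figure D1:**
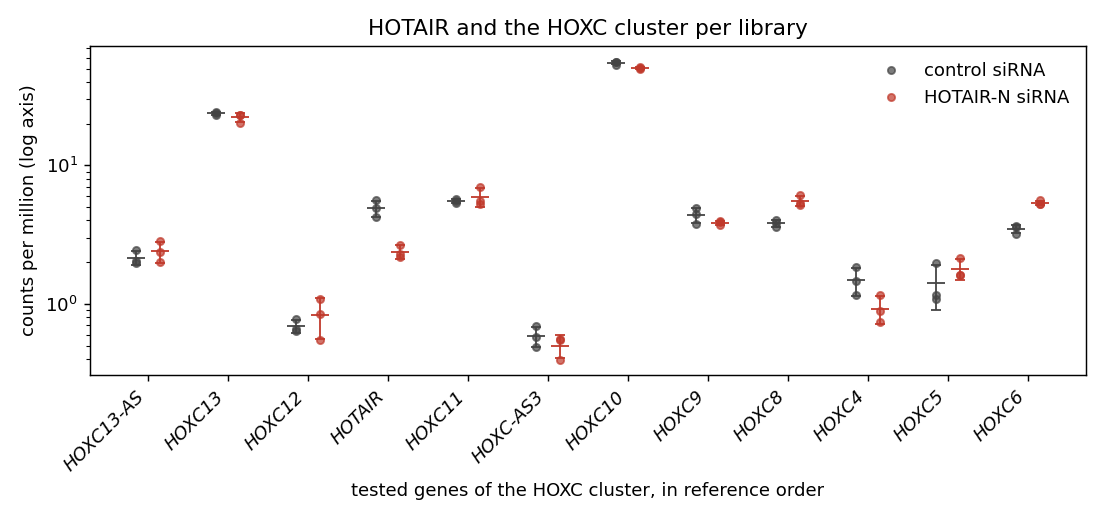
CPM, on a log axis, of the 12 tested HOXC cluster genes in their reference order, with 3 points per siRNA and the mean and SD as bars. HOTAIR lies at 4.90 CPM with control siRNA and 2.39 CPM with HOTAIR-N siRNA, and the libraries of the groups do not overlap.

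Among genes past the threshold with a mean log2 CPM of at least 1, a length of at least 200 nt and no overlap between the groups, CACNG4, a calcium channel subunit, fell the most, from 15.8 ± 1.86 to 1.54 ± 0.14 CPM (SD, n = 3 each), a log2 fold change of -3.36 (SE 0.12). GSTP1, a glutathione transferase, fell from 794.5 ± 67.5 to 113.2 ± 5.54 CPM (SD, n = 3 each), and PPIB, the endoplasmic reticulum cyclophilin B, from 260.1 ± 14.6 to 46.7 ± 2.49 CPM (SD, n = 3 each). Also among the 12 lowest were CCDC3, the leptin receptor LEPR, MBD5, the ETS factor ERG, WIPF1, NT5DC1, TVP23C-CDRT4, C8orf59 and STAC, with log2 fold changes from -2.99 to -2.29. CD38, an NAD-consuming surface enzyme, rose the most among these genes, from 0.46 ± 0.05 to 3.53 ± 0.60 CPM (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.20). EREG, which encodes the EGFR ligand epiregulin, rose from 42.7 ± 4.61 to 200 ± 8.63 CPM (SD, n = 3 each), and TMEM75, OAS1, TMEM255A, the neurotrophin receptor NGFR, SLC22A4, LINC00472, ANKRD34A, TRANK1, LAMA4 and CES4A rose by 2.87 to 2.21 on the log2 scale.

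In total 8672 of 15072 tested genes (57.5%) differed, with 4326 higher and 4346 lower with HOTAIR-N siRNA (edgeR quasi-likelihood test). Most differences were small. Among the changed genes the median absolute log2 fold change was 0.46, and 651 rose and 655 fell by 2-fold or more. The groups did not overlap for 9476 genes (62.9%), where chance gives 10%. DESeq2, limma-voom and all scalings gave counts within 1.5 times of this one. A test against a fold of 1.5 called 1700 genes, with 830 higher and 870 lower.

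**Figure D2:**
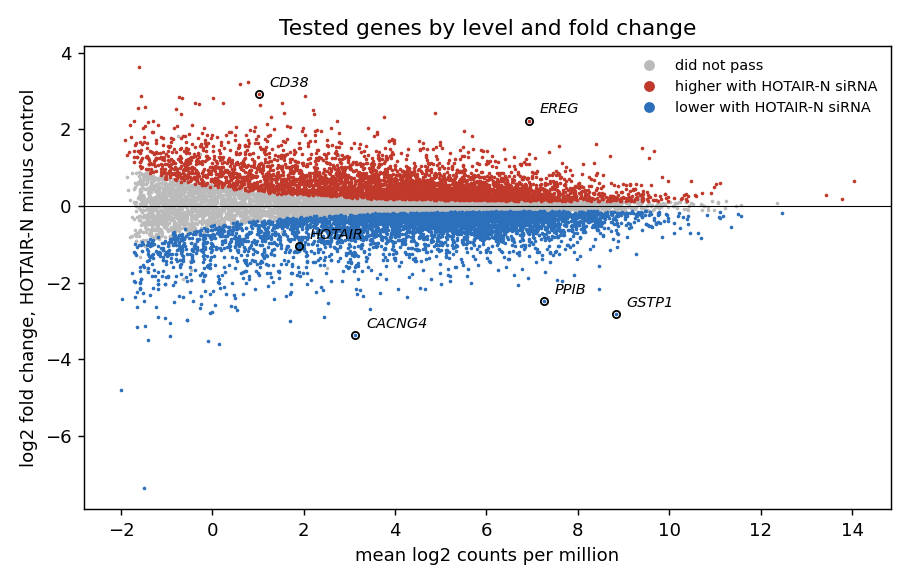
Mean log2 CPM on the horizontal axis against the log2 fold change, HOTAIR-N siRNA minus control siRNA, for the 15072 tested genes, each a point coloured by whether it passed and in which direction. GSTP1 and PPIB stand out among abundant genes, at -2.81 and -2.48, and HOTAIR lies at -1.04.

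Some of the changed genes carried a short sequence in common. The word GACCAAT in the 3' UTR went with lower expression more than any other 7-base word (z = -17.2, 860 genes). Grouped by sites that were chosen after the scan was seen, genes with GACCAATA in the 3' UTR had a median log2 fold change of -0.40 (250 genes), those with GACCAAT alone -0.31 (610 genes), those with ACCAATA alone -0.13 (806 genes) and those without these or ACCAAT 0.04 (10047 genes). By the base that followed GACCAAT, the medians were -0.40 (A), -0.41 (C), -0.29 (G) and -0.34 (T). GSTP1, PPIB, NT5DC1 and C8orf59 carried GACCAAT or ACCAATA in the 3' UTR and WIPF1 in the coding sequence. CACNG4, CCDC3, LEPR, MBD5, ERG, TVP23C-CDRT4 and STAC did not. These carriers are 41.67% of the 12 lowest genes, against 21.32% of all genes searched. Among the 12 highest, OAS1 and LAMA4 carried GACCAAT or ACCAATA in the coding sequence. In the opposite direction GAATATA went with higher expression (z = 9.86, 1999 genes). Here the median log2 fold changes were 0.03 for TGAATATA (914 genes), -0.02 for TGAATAT alone (1725 genes), 0.04 for GAATATA alone (740 genes), -0.06 for GAATAT alone (1467 genes) and 0.0026 for genes without these (8452 genes). The z values rest on fold changes with the trend with UTR length and GC content removed, and the medians given above do not. With it removed, the median of genes with GAATATA minus that of genes without it was 0.13, and for GACCAAT -0.28. In coding sequences GACCAAT had the lowest z of all words (-9.20). GAATATA had z = 3.05 there and rank 77 among words that went with higher expression.

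Genes of cell division fell with HOTAIR-N siRNA. Of 50 tested genes of G2 and mitosis, 47 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone, and a median log2 fold change of -0.53. CDCA8, a subunit of the chromosomal passenger complex, fell by 1.31 on the log2 scale (SE 0.06), the mitotic kinesin KIF23 by 1.05 (SE 0.06), the cytokinesis protein gene ANLN by 0.87 (SE 0.05) and KIF4A by 0.70 (SE 0.05). Of 45 S phase and DNA replication genes, 22 fell, 5 rose and 18 did not pass, and SLBP, MCM6, DTL and E2F8 fell by 0.85, 0.51, 0.52 and 0.54. Of 43 replication-dependent histone genes, 25 rose, 1 fell and 17 did not pass, or 26 and 1 adjusted over the list alone, and HIST1H1C, HIST2H2AA3, HIST1H2BD and HIST2H2BE had log2 fold changes of 1.83, 1.71, 1.52 and 1.45. RMRP, RPPH1 and SCARNA2, which have no poly(A) tail, had 0 to 8 expected counts per library, and histone genes are close copies of each other. Of the G2 and mitosis genes, 29 of 50 carried at least 1 of the words GACCAAT, ACCAATA, TGAATAT and GAATATA in the 3' UTR or coding sequence, and of the interferon response genes 14 of 32, against 5979 of all 13298 genes searched. These counts pool words that went with lower and with higher expression. KIF23 and ANLN carried only TGAATAT or GAATATA, KIF4A carried words of both kinds, and CDCA8 carried none. Camera called all 3 lists with the preset correlation (adjusted p = 3.11e-12, 0.0286 and 2.78e-06). With an estimated correlation none passed (adjusted p = 0.509, 0.397 and 0.53), the histone median went from 0.80 to 0.44 with the length and GC trend removed, and the S phase list also missed the threshold without its word-carrying members (adjusted p = 0.136).

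Genes of innate immunity and inflammation rose. Of 32 tested interferon response genes, 26 rose, 1 fell and 5 did not pass, or 26 and 2 adjusted over the list alone. PARP9, PARP14, PARP12 and the immunoproteasome subunit gene PSMB8 had log2 fold changes of 1.99 (SE 0.12), 1.74 (SE 0.09), 1.33 (SE 0.07) and 1.11 (SE 0.07). Chosen after their values were seen, MX1 and IFIT3 had 2.10 and 1.81, whereas ISG15 (0.18) did not pass. Of 28 NF-kB and inflammatory mediator genes, 22 rose, 2 fell and 4 did not pass, with the same counts adjusted over the list alone. The chemokine gene CCL20 rose from 165.6 ± 9.61 to 507.9 ± 30.2 CPM (SD, n = 3 each), and CXCL8, CCL2 and TNFAIP3 had log2 fold changes of 1.48, 1.43 and 1.05. Of 37 apoptosis regulators, 19 rose, 5 fell and 13 did not pass, or 20 and 5 adjusted over the list alone. PMAIP1 (1.24) and BIRC3 (0.68) rose, while BCL2 (-1.75) and BIRC5 (-0.61) fell. Camera called these 3 lists with the preset correlation (adjusted p = 4.25e-08, 2.46e-06 and 0.018) and not with an estimated one (adjusted p = 0.101, 0.341 and 0.341), and the apoptosis list also missed the threshold without its word-carrying members (adjusted p = 0.0993).

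A further 5 lists passed the same test. Of 39 genes of collagens and matrix enzymes, 21 rose, 3 fell and 15 did not pass, and COL1A1, MMP1, COL4A2 and LOXL2 had log2 fold changes of 1.66, 1.71, 0.99 and 0.71. Of 15 neuroendocrine markers only 6 were tested. Of these, 5 rose, with SYP at 1.89, CHGB at 1.13, UCHL1 at 1.09 and ENO2 at 0.79, and 1 did not pass. Of 8 HOXB genes, 6 rose and 2 did not pass, with HOXB9 at 1.40, HOXB4 at 0.79, HOXB3 at 0.60 and HOXB7 at 0.44. Of 82 ribosomal protein genes, 56 rose, 7 fell and 19 did not pass, or 57 and 7 adjusted over the list alone. The median of this list was 0.19, and 0.01 with the length and GC trend removed. The members with the smallest p went both ways, with RPL23A at 0.55 and RPL13A, RPL19 and RPL7L1 at -0.88, -0.82 and -0.54. RPL13A and RPL7L1 carry GACCAAT or ACCAATA in the 3' UTR and RPL19 in the coding sequence, while RPL23A carries TGAATAT or GAATATA in the 3' UTR. Of the 59 ribosomal protein genes without a word, 10 of them not searched, 44 rose and 1 fell. Of 33 ATF4 and amino acid genes, 20 fell, 9 rose and 4 did not pass, and ATF5, WARS and MTHFD2 fell by 1.52, 0.62 and 0.62 while CTH rose by 1.52. Except where given, counts adjusted over the list alone were the same. Camera gave adjusted p = 0.00287, 0.00226, 0.0181, 0.00208 and 0.039 in this order, and with an estimated correlation adjusted p = 0.53, 0.509, 0.515, 0.763 and 0.654. The neuroendocrine list did not pass with no filter on low counts (adjusted p = 0.086), nor the ribosomal protein list with fry (adjusted p = 0.133). The ATF4 list did not pass when control replicate 1 (adjusted p = 0.0748) or 2 (0.0609) or HOTAIR-N siRNA replicate 1 (0.0594) or 3 (0.0613) was left out.

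**Figure D3:**
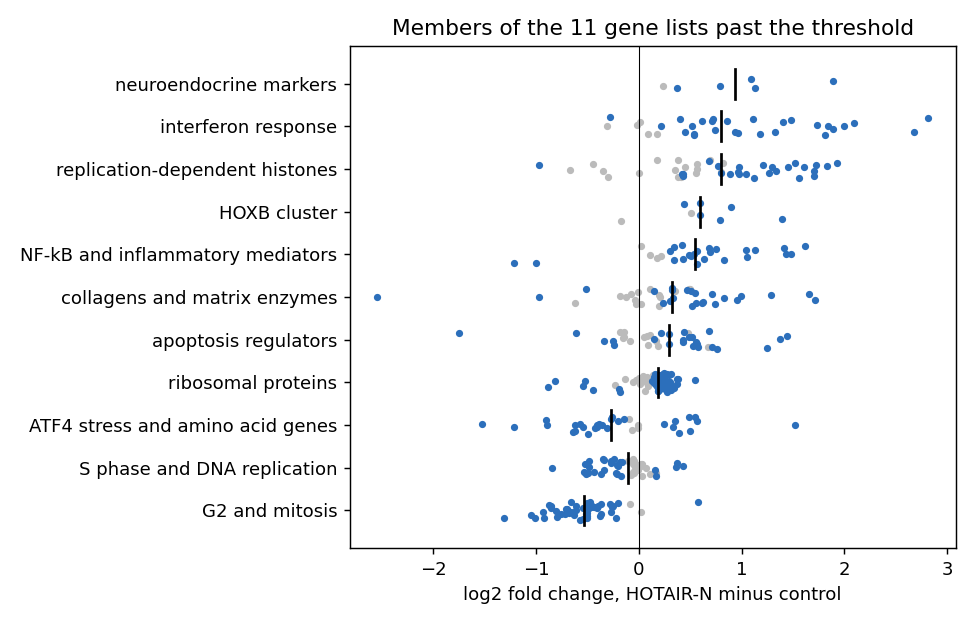
Log2 fold changes, HOTAIR-N siRNA minus control siRNA, of the tested members of the 11 gene lists past the threshold of camera with its preset correlation. Blue points passed the test per gene, grey points did not, and black bars are medians, from -0.53 for G2 and mitosis to 0.94 for neuroendocrine markers.

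Genes that earlier work ties to HOTAIR, and the complexes it is known to bind, moved in both directions. Of 5 tested genes on the list of genes repressed through HOTAIR, CDKN1A (0.92), HOXD10 (0.60) and PCDH10 (0.43) rose and JAM2 (-1.10) fell. JAM2, at 0.97 CPM with control siRNA, carries GACCAAT or ACCAATA in the 3' UTR. CDKN1A and PCDH10 carry TGAATAT or GAATATA there. PCDH10 did not pass without control replicate 2 (adjusted p = 0.103) or 3 (0.0547) or HOTAIR-N siRNA replicate 1 (0.0677) or 2 (0.175), or with DESeq2 (0.121). Of the genes listed as induced, SNAI1 (0.62) rose, and LAMB3 (0.53) and ABL2 (0.03) did not pass. ABL2, which carries GACCAAT or ACCAATA in the 3' UTR, passed at 0.11 with the length and GC trend removed (adjusted p = 0.0118). Of 20 genes of PRC2 and LSD1-CoREST, the chromatin complexes, 10 fell, 4 rose and 6 did not pass, or 11 and 4 adjusted over the list alone. The median was -0.14, and 0.11 over the 11 members without a word, of which 4 rose and 3 fell. SUZ12, which carries a word in the 3' UTR and coding sequence, fell from 155.4 ± 15.9 to 74.3 ± 4.42 CPM (SD, n = 3 each). PHF19 and EZH2 fell by 0.81 and 0.71 on the log2 scale while JARID2 rose by 0.56. EZH2 carries GACCAAT or ACCAATA in the coding sequence, and PHF19 and JARID2 carry no word. In the HOXD cluster HAGLR (-0.91) and HOXD1 (-1.07) fell and HOXD10 rose, and in the HOXA cluster HOXA11, HOXA11-AS and HOXA10 rose by 1.13, 1.29 and 0.98. Camera called none of these lists that it tested (adjusted p from 0.211 to 0.923).

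Epithelial and mesenchymal genes did not separate by direction. Of 24 epithelial markers, 10 rose and 3 fell, with CDH1 at 1.07, CDS1 at 1.04 and KRT18 at -0.71. Of 26 mesenchymal markers, 11 rose and 7 fell, with TNC at 0.76, ITGA5 at 0.70 and FN1 at -0.72. Of 35 laminins and integrins, 16 rose and 9 fell, or 16 and 11 adjusted over the list alone, with LAMA1 at 1.22 and PTK2 at 0.93. The median of the laminins and integrins was 0.22, and -0.14 over the 12 members without a word, of which 4 rose and 3 fell. Camera gave adjusted p = 0.168, 0.774 and 0.219.

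The remaining lists did not pass camera either (adjusted p from 0.0582 to 0.945). Under some alternatives the RAS-MAPK list passed (no filter, adjusted p = 0.0329, and without control replicate 1, 0.0312), as did the OXPHOS list (without control replicate 1, 0.0275, and without word-carrying members, 0.026) and the glycolysis and hypoxia list (without word-carrying members, 0.0342). Of 15 genes of the RNA interference machinery, 9 fell and 2 rose, or 10 and 4 adjusted over the list alone, with TSNAX at -1.20, DICER1 at -0.70, DROSHA at -0.64 and XPO5 at -0.59. Of 20 heat shock genes, 10 fell and 2 rose, with HSPD1 at -0.48. Of 27 YAP targets, 14 fell and 5 rose, with CTGF at -0.84 and AMOTL1 at 1.10. Of 34 RAS-MAPK feedback genes, 18 rose and 7 fell, with DUSP2 at 1.49 and SPRED2 at -0.84. Of 31 p53 targets, 13 rose and 7 fell, with BTG2 at 0.83. Of 32 TGF-beta targets, 13 rose and 10 fell, with JUNB at 1.04 and TGFBR2 at -1.04. Of 36 glycolysis and hypoxia genes, 13 rose and 10 fell, with SLC2A3 at 1.52 and PFKFB3 at -1.64. Of 27 NRF2 targets, 11 rose and 7 fell, with FTH1 at 0.64 and SRXN1 at -0.92. Of 19 NOTCH targets, 9 rose and 5 fell, with NOTCH2 at -1.08. Of 23 WNT targets, 8 rose and 6 fell, with DKK1 at 0.61. Of 27 unfolded protein response genes, 10 rose and 8 fell, with CALR at 0.58 and HSPA5 at -0.42. Of 19 SREBP1 targets, 9 rose and 8 fell, with SCD at 0.52 and ACACA at -0.72. Of 24 SREBP2 targets, 5 rose and 7 fell, with ACAT2 at -0.70. Of 40 MYC and ribosome biogenesis genes, 11 rose and 7 fell, with POLR1B at -1.11. Of 86 nuclear-encoded OXPHOS genes, 30 rose and 11 fell, with COX7A2 at -1.06. Adjusted over the list alone, 13 and 7 NRF2 targets, 10 and 5 NOTCH targets, 9 and 5 MYC and ribosome biogenesis genes and 30 and 10 OXPHOS genes rose and fell, and for the other lists with no second count given the counts were the same. Of 20 small nuclear, 7SL and 7SK RNAs, 8 were matched and 0 had enough counts to be tested. The mitochondrial ribosomal RNAs RNR1 and RNR2 rose by 0.61 and 0.66.

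Markers of the lung lineage and of other cell types were examined too. Of 25 lung lineage markers 9 were tested, and ABCA3 (0.62), NKX2-1 (1.02) and LAMP3 (0.66) rose. Of 12 fibroblast markers 8 were tested, and COL1A1, LUM (0.96) and POSTN (0.50) rose, POSTN not passing without HOTAIR-N siRNA replicate 2 (adjusted p = 0.0618). Of 15 blood and endothelial markers 4 were tested, and VWF rose from 0.27 to 0.54 CPM, not passing without control replicate 1 (adjusted p = 0.0517) or with DESeq2 (0.0842). CD14, CD68 and CDH5 did not pass, CD68 passing without control replicate 1 (adjusted p = 0.0381).

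At the level of isoforms, some genes changed in composition while their total did not pass. The NM_001277062 isoform of MFF, a mitochondrial fission factor, went from 19.1 ± 1.67% to 55.0 ± 0.59% of the gene (SD, n = 3 each), and NM_199282 of ARHGAP27 from 61.0 ± 5.69% to 94.9 ± 1.17% (SD, n = 3 each). NM_003574 of VAPA and NM_001191007_2 of SRSF10 rose by 1.66 and 2.38 on the log2 scale. By isoform use, NIN, PPP2R5C, WNK1, DCAF6 and STAU2 had the smallest p. Of these, NIN (-0.77), WNK1 (-0.29) and DCAF6 (0.74) also passed in total on the log2 scale, and PPP2R5C and STAU2 did not. NM_014823 of WNK1 went from 46.6 ± 2.50% to 24.3 ± 1.31% of the gene (SD, n = 3 each), and NM_014393 of STAU2 from 32.8 ± 3.76% to 63.8 ± 1.67% (SD, n = 3 each). NM_001164381 of STAU2, NM_182946 of NIN and NM_001352912 of PPP2R5C made up 35.1%, 13.3% and 14.7% with control siRNA and were listed at 0 in all 3 HOTAIR-N siRNA libraries.

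In total 6362 of 32627 tested isoforms differed, with 3064 higher and 3298 lower, and isoform use differed in 311 of 7523 genes, 99 of which did not change in total. DESeq2 called 10040 isoforms. Leaving out control replicate 2 or 3 gave 4225 or 4198 isoforms, and leaving out HOTAIR-N siRNA replicate 1, 2 or 3 gave 4214, 3696 or 3551. Isoform use differed in 202 genes without a filter, 632 with 10 counts in every library, 183 over isoforms with at least 10% of their gene, and 186 or 205 without control replicate 3 or HOTAIR-N siRNA replicate 3.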

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

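The alternatives with the length and GC trend removed and with word-carrying list members left out were chosen after the data were seen. HOTAIR kept its direction and its side of the threshold under every alternative run for it, the test against a fold of 1.5 not being among them, with log2 fold changes from -1.14 to -0.94. The count of changed genes stayed between 7503 and 10080 except against a fold of 1.5, a stricter question, with 1700 genes (830 higher, 870 lower), and none of the shared calls changed sign except 12 with the length and GC trend removed. Of 11 shifted lists, 0 passed with an estimated correlation (lowest adjusted p = 0.1), and fry, which does not compare a list with other genes, called 26. Among isoforms, DESeq2 called 10040 isoforms, leaving out single libraries gave 3551 to 5647, and isoform use gave 202 genes with no filter, 632 with the stricter filter, 183 over isoforms with at least 10% of their gene and 186 to 251 without single libraries. Whether fewer samples or traits of single libraries lowered the counts without a library was not tested. Without control replicate 1 the count of changed genes was higher than with all libraries, at 9234, and 5647 isoforms passed. The replicate numbers were not taken to pair the samples, since the correlations of same-numbered libraries were -0.121, 0.0209 and -0.0385, and not every library correlated best with its own number. With the replicate number as a block 7984 genes, 2012 isoforms, 141 genes by isoform use and 9 lists passed, and the S phase list (adjusted p = 0.0509), the ATF4 list (0.0647) and PCDH10 (0.0568) did not. Of 180 named genes besides HOTAIR, 4 lost their call under some alternative (HOXC4, PCDH10, VWF, POSTN) and 10 gained one. ABL2 and HOXC11, which did not pass, changed sign, ranging from -0.020 to 0.091 and from -0.041 to 0.171 without single libraries. The 6 lists whose direction turned did not pass in the main test. Their mean difference from all genes, with the direction of camera or fry in some cases opposite to it, was 0.161 (HOXC), 0.033 (TGF-beta) and 0.061 (WNT) with no filter, -0.0132 (TGF-beta) and 0.037 (WNT) with the stricter filter, -0.033 (HOXC) with the block, -0.032 (HOXC) and 0.039 (TGF-beta) with fry, and 0.00143 (PRC2), -0.0165 (MYC) and -0.048 (WNT) without word-carrying members. Without single libraries it ranged from -0.074 to 0.0175 for HOXC, -0.126 to -0.024 for HOXD, -0.00422 to 0.057 for TGF-beta, -0.000377 to 0.032 for MYC and -0.0996 to -0.043 for WNT, and the cause was not tested.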

Other observations

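The tests of genes without a seed word or a 6-base site, the choice of the sites that count as a word, the alternatives that removed a trend or word-carrying list members, and the non-coding RNAs described first were chosen after the main results were seen.

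NEAT1, the RNA scaffold of nuclear paraspeckles, had 4390, 4420 and 4636 expected counts in the control libraries and 9298, 9140 and 9779 with HOTAIR-N siRNA. Summed over all replication-dependent histone genes, expected counts were 6682 to 7957 in the control libraries and 13224 to 14835 with HOTAIR-N siRNA. RMRP, RPPH1 and SCARNA2, which have no poly(A) tail and are 268 to 420 nt long, had 8 expected counts or fewer in each library. GAPDH had 325992 or more, and MALAT1, of 8342 nt, had 1473 to 3453. The labels name a total RNA kit, and these short RNAs alone do not tell how the RNA was selected.

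Of the tested genes 57.5% differed, and 1 candidate source is pairing of siRNA seeds with the 3' UTRs of other mRNAs. GACCAAT had z = -17.17. This was 3.60 times the z of AGATCAA (-4.773), the strongest unrelated word that went with lower expression. This is what such pairing by the HOTAIR-N siRNA would give in the genes that carry it. In the longest of 5 annotated HOTAIR transcripts GACCAAT has 1 site and GAATATA 2, and the others hold neither. That does not decide the source, since 12.9% of all 7-base words occur in that transcript and the siRNA sequences are not given. For the control siRNA the test did not decide, because the scan was run 2 times and GAATATA had z = 9.855 over all 13298 genes and 10.35 over the 12172 with a mean log2 CPM over 0, on either side of a bound of 10 that had been set without naming a filter. Direct pairing at these words does not cover the rest, since 56.32% of genes with neither word in the 3' UTR or coding sequence differed too (63.3% of genes with one). So did 54.27% of the 4647 genes with neither ACCAAT nor GAATAT there (62.2% of genes with one). These shares pool the words and both directions. At sites chosen after the scan was seen, 60.0% of genes with GACCAATA in the 3' UTR were called lower. Of genes without it, GACCAAT, ACCAATA or ACCAAT there, 26.08% were called lower. Removing a trend with length and GC content left 10080 changed genes, which argues against that trend, while effects that follow from paired genes and the loss of HOTAIR stay open, since 1 siRNA per target cannot separate them.

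For the G2 and mitosis and the interferon response genes, words in the members themselves may be a source of the shift. Against this, the members without a word had medians of -0.507 over 21 genes, all of which fell, and 0.624 over 18 genes, of which 13 rose. A trend with length and GC content is argued against too, since with it removed the medians were -0.51 and 0.84. Effects that follow from other paired genes, a response to the siRNA duplex and the loss of HOTAIR stay open and were not tested.

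The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and each other split still holds part of the difference between the siRNAs. The real split, 1 of 10, gave 8672 genes, 6362 isoforms, 311 genes with changed isoform use and 11 lists, and the highest of the others gave 0, 0, 33 and 9. Camera with its preset correlation called both the G2 and mitosis and the interferon lists in all 9 other splits.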
